A study of Mus musculus with 18 samples.

How the data were processed

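The data are read counts per gene of bulk RNA-seq libraries from macrophages sorted out of the mouse brain, 18 in all. Libraries were made with a low-input kit that amplifies full-length cDNA by PCR and were read as pairs on an Illumina instrument, per the labels' protocols. The submitters' processing notes name DRAGEN, DESeq2 and mm10, with no version and no role. The aligner settings, the gene annotation and the handling of strand are not given in the sources used here. Without a stated strand, reads of overlapping or antisense genes cannot be assigned to either, and near-identical gene copies such as Hba-a1 and other globin genes may share reads. The authors deposited a table of whole-number counts per gene, which is the input of every test here, and a table of CPM, in which the deposited counts were divided by library totals. The deposited CPM table was not used. All columns of the count table could be assigned to a sample by name, and 0 columns belonged to other samples.

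The table held 55774 rows and 55487 distinct genes. Coordinates are those of the GRCm38 (mm10) annotation, counted from 1. Groups were taken from the sample labels: tdTomato+ and tdTomato- cells of young and old mice, and GFP+ and GFP- cells after BMT. The treatment of the tdTomato mice and the ages of the BMT mice are not given library by library. Library totals were 25581738 to 45309496 counts and TMM factors 0.948 to 1.049. Levels are CPM scaled by these factors, as mean ± SD. Since PCR copies are not independent molecules, counting error understates the error of each library, and the replicates carry the tests. The groups hold 2 to 4 libraries, so a difference with a large spread may be missed.

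Tests used R 4.3.3, edgeR 4.0.16 and limma 3.58.1, with DESeq2 1.42.0 as an alternative. Genes were kept by filterByExpr with the 6 groups (minimum count 10, minimum total 15), leaving 20432. A single quasi-likelihood model with robust dispersion was fitted over the 18 libraries with a mean for each group, leaving 12 residual degrees of freedom, and the biological coefficient of variation was 0.379. From it 10 comparisons were taken: the tdTomato effect averaged over ages, in young and in old mice and its difference between ages, GFP+ against GFP-, GFP+ against tdTomato+, GFP- against tdTomato-, the difference of the label effects between models, and old against young in each tdTomato state. P-values were adjusted by the Benjamini-Hochberg method over the genes of each comparison, with a threshold of 0.05 and no minimum fold. Where comparisons average the ages, each age has equal weight. A gene with 1 to 3 counts in all on a side of a comparison is given as levels.

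Gene lists for 19 pathways and 16 cell types were fixed in advance and tested with camera at a preset correlation of 0.01, again with a correlation estimated for each list, and with fry. Adjustment was over the 35 lists of each comparison. Of 126 list calls with the preset correlation, 35 held with an estimated correlation, 4 of 12 for tdTomato+ against tdTomato- and 10 of 22 for GFP+ against GFP-. Genes were named by a fixed rule. For each comparison it took up to 10 higher and 10 lower genes with the smallest adjusted p among those with an absolute log2 fold change of at least 1, a mean log2 CPM of at least 3 and no overlap between the libraries compared, leaving out predicted genes, small RNAs, receptor segments and sex-linked genes. It added up to 4 members of each list by adjusted p and 12 genes chosen in advance, among them P2ry12, Sall1, Ms4a7 and Cdkn1a. Principal components used the 500 most variable genes on the log2 CPM scale with a prior count of 2.

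The GFP+ and GFP- libraries share pools of mice according to the labels. Over 8779 genes with a mean log2 CPM of at least 3 the deviations from the group means correlated at 0.225, 0.235 and 0.182 for the 3 pairs that share mice. The tests were repeated with that pairing, and the replicate numbers of the tdTomato libraries, as a block. Other alternatives were DESeq2, limma-voom with sample quality weights, edgeR with RLE factors, no filter and a stricter filter on low counts (5 CPM in 3 libraries), fits on the compared groups alone, and leaving out each library in turn. A term for the library series and fits without 2 libraries rich in choroid plexus transcripts were added after seeing the data. The series term sets the tdTomato libraries numbered 15 to 21 against all other libraries, the BMT libraries included.

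The scripts were tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. In the simulation of tdTomato+ against tdTomato- over 19605 genes, edgeR recovered 44 of the 2-fold and 63 of the 4-fold genes and 1.83% of its calls were false. For GFP+ against GFP- over 19603 genes it recovered 29 and 56 (2.3% false), for GFP- against tdTomato- over 19604 genes 44 and 54 (5.77% false), for old against young tdTomato+ cells over 19623 genes 31 and 56 (5.43% false), and for old against young tdTomato- cells over 19619 genes 26 and 47 (1.35% false).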

Results

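RNA was sequenced in bulk from macrophages sorted out of the mouse brain, in 18 libraries. All cells passed a gate for live cells positive for CD45 and CD11b and negative for Ly6C, Ly6G, CD206 and CD44. Ly6C and Ly6G mark monocytes and neutrophils, and CD206 marks macrophages of the brain borders. The reporter then divided the gated cells. In the first model, Cre recombinase driven by Ms4a3, a gene of granulocyte and monocyte progenitors, switched on tdTomato, so that cells descended from these progenitors are tdTomato+. These mice were young or old, with no ages in numbers, and gave 3 young tdTomato+, 2 young tdTomato-, 4 old tdTomato+ and 3 old tdTomato- libraries. By elimination in the labels they were the mice given PLX5622, an inhibitor of the CSF1 receptor that depletes microglia. The second model was irradiation and transplantation of bone marrow (BMT) that expresses GFP under the ubiquitin C promoter, with 2 libraries of GFP+ donor cells and 4 of GFP- host cells, each made from a pool of mice. The libraries held 25581738 to 45309496 counts over 55487 genes, of which 20432 were tested. Replicates of a group correlated at r = 0.948 to 0.982 across genes, which are not independent replicates, and no pair agreed within sampling noise. The titles count the tdTomato libraries as mice within each state, but they count the BMT pools in the same way, so the p-values were read as measuring the spread between libraries.

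Reporter state separated the libraries first. The first principal component, holding 48.1% of the variance of the 500 most variable genes, ran from the GFP- cells (scores -57.3 to -52.8) through the tdTomato- cells (-31.9 to -14.9) to the tdTomato+ cells (23.5 to 44.2) and the GFP+ cells (46.8 to 47.2). The second component, with 27.6% of the variance, placed the GFP+ cells at 71.1 to 74.6 and the other 16 libraries at -31.4 to 19. Young and old libraries were interleaved among the tdTomato+ cells. On the first component these cells divided by library series, at 35.4 to 44.2 for the earlier and 23.5 to 28.2 for the later numbers. Among tdTomato- libraries only young library 2 belongs to the earlier series, so series and reporter are not balanced. With the series as a term, edgeR called 3962 genes for tdTomato+ against tdTomato-, against 4367 without it. Over all tested genes the first component held 29.1%.

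**Figure D1:**
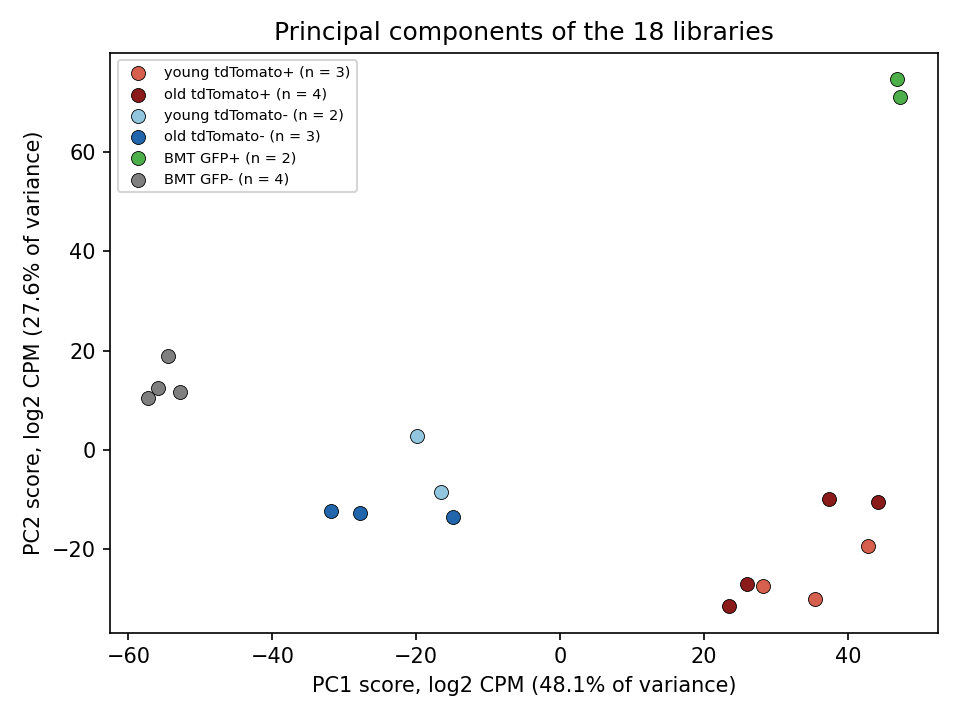
Scores of the 18 libraries on the first and second principal components of log2 CPM, with 1 point per library coloured by group. The 7 tdTomato+ libraries lie at 23.5 to 44.2 on the first axis and the 5 tdTomato- libraries at -31.9 to -14.9, while the 2 GFP+ BMT libraries stand apart on the second axis.

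The comparison of tdTomato+ with tdTomato- cells asked how macrophages of bone marrow origin differ from other macrophages of the same gate. The tdTomato+ cells had less of the transcripts that define microglia. P2ry12, the purinergic receptor of resting microglia (ENSMUSG00000036353, GRCm38/mm10 chromosome 3, 59216272 to 59262871), was at 1195 ± 335 CPM (SD, n = 7) against 5158 ± 847 CPM (SD, n = 5). Sall1, a transcription factor of microglial identity (ENSMUSG00000031665, chromosome 8, 89027235 to 89044162), was at 18.3 ± 17.4 CPM (SD, n = 7) against 457 ± 75.6 CPM (SD, n = 5). Conversely, Ms4a7 (ENSMUSG00000024672, chromosome 19, 11321039 to 11336146) was at 1213 ± 151 CPM (SD, n = 7) against 152 ± 79.3 CPM (SD, n = 5), and the lectin receptor gene Clec12a (ENSMUSG00000053063, chromosome 6, 129342691 to 129365303) at 249 ± 51.9 CPM (SD, n = 7) against 29.2 ± 19.3 CPM (SD, n = 5). Apoe, which encodes a lipid carrier, reached 18480 ± 10070 CPM (SD, n = 7) in tdTomato+ cells against 1208 ± 648 CPM (SD, n = 5).

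In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, averaged over both ages, 2170 genes were higher and 2197 lower in tdTomato+ cells, of which 995 and 995 changed at least 2-fold. The smallest adjusted p-values, all 4.19e-10 by edgeR, belonged to Arhgap19 (log2 fold change 2.19 ± 0.11 SE), a Rho GTPase-activating protein gene, Tmem176b (1.82 ± 0.10), Pmp22 (-2.34 ± 0.12), the sodium-potassium-chloride cotransporter gene Slc12a2 (-2.87 ± 0.15), Plcl1 (-3.16 ± 0.16), Selplg (-2.51 ± 0.13), which encodes the P-selectin ligand, and Lpcat3 (-1.63 ± 0.08). Arhgap19 (ENSMUSG00000025154, chromosome 19, 41766588 to 41802047) was at 390 ± 46.1 CPM (SD, n = 7) against 85.8 ± 15.2 CPM (SD, n = 5). The chemokine receptor gene Cxcr3 was higher by 2.42 on the log2 scale (edgeR adjusted p = 1.03e-09).

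The homeostatic microglia list, fixed like all lists before the data were examined, had 18 of 20 tested members lower, 1 higher and 1 that did not pass, and the same counts when adjusted over the list alone. Tmem119 fell by 1.07 on the log2 scale (edgeR adjusted p = 5.26e-07), P2ry12 by 2.13 (2.72e-08) and Sall1 by 4.68 (0.00212). The member that rose was Fcrls, a microglial Fc receptor-like gene, at 3797 ± 374 CPM (SD, n = 7) against 2215 ± 152 CPM (SD, n = 5). Of the list of genes of engrafted brain macrophages, 13 of 15 rose and 2 did not pass (13 adjusted over the list alone), among them Ms4a7 (log2 fold change 2.97 ± 0.31 SE, edgeR adjusted p = 5.07e-06) and Lyz2, the lysozyme gene (3.55 ± 0.37, 4.67e-06). Genes of border-associated macrophages rose in 11 of 13 cases with 2 not passing (11 adjusted over the list alone). They included Dab2 (2.65, edgeR adjusted p = 5.25e-08) and Mrc1, which encodes the CD206 protein that the gate excluded, at 474 ± 156 CPM (SD, n = 7) against 46.3 ± 33.7 CPM (SD, n = 5). Chemokine and adhesion receptors rose in 8 of 14 cases, fell in 2 and did not pass in 4 (8 and 2 adjusted over the list alone). In limma's camera test these 4 lists had adjusted p of 3.6e-17, 7.01e-20, 1.39e-12 and 0.000286, and each passed with an adjusted p of 0.0213 with an estimated correlation.

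Interferon response genes rose in 18 of 21 cases and 3 did not pass (19 higher adjusted over the list alone), with Bst2, which encodes tetherin, higher by 1.81 and Oasl2 by 1.44 on the log2 scale. The camera call for this list (1.51e-11) was lost at adjusted p = 0.146 with an estimated correlation. MHC class I genes rose in 9 of 12 cases with 3 not passing (9 adjusted over the list alone), and this call (1.24e-06) was lost at adjusted p = 0.0693 with an estimated correlation. For MHC class II presentation 7 of 10 members rose, 2 fell and 1 did not pass (7 and 2 adjusted over the list alone), and the call (0.000145) was lost at adjusted p = 0.33 with an estimated correlation. Its H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) was at 1658 ± 693 CPM (SD, n = 7) against 270 ± 91.6 CPM (SD, n = 5). In the disease-associated microglia list 9 of 20 members rose, 5 fell and 6 did not pass (12 and 5 adjusted over the list alone). Axl (1.90 on the log2 scale) and the growth factor gene Igf1 (2.96) were among those higher and Cd9 (-2.05) among those lower. Its camera call (0.0168) was lost at adjusted p = 0.33 with an estimated correlation. Lysosomal genes rose in 9 of 18 cases, fell in 2 and did not pass in 7 (11 and 2 adjusted over the list alone), and that call (0.000975) was lost at the same adjusted p = 0.33 with an estimated correlation. Beside these groups, 5 of 6 erythroid markers were higher and 1 did not pass (6 adjusted over the list alone), with Alas2, the heme synthesis enzyme of red cell precursors, at 110 ± 67.9 CPM (SD, n = 7) against 34.8 ± 22.9 CPM (SD, n = 5). This call (0.000975) was lost at adjusted p = 0.33 with an estimated correlation. T and NK cell markers were higher in 2 of 10 cases and 8 did not pass (2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.397). Its mean log2 CPM moved with the series that the library numbers form, at -0.449 to 1.738 in tdTomato+ libraries numbered 8 to 13 and -3.338 to -1.534 in those numbered 15 to 21. Astrocyte markers were higher in 6 of 9 cases, lower in 1 and not past the test in 2 (6 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.103). Its Aldoc, a glycolytic enzyme gene, rose by 1.86 on the log2 scale (edgeR adjusted p = 2.56e-06), and the member that fell was Slc1a3, a glutamate transporter gene (-3.92, 3.82e-06). Mki67, a proliferation marker, did not pass (edgeR adjusted p = 0.0513). It passed with DESeq2 (0.034), with no filter on low counts (0.0155) and without the young tdTomato+ library 3 (0.034), the old tdTomato+ libraries 3 (0.0325) and 5 (0.0353) or the old tdTomato- library 3 (0.0264), within a range from 0.0155 to 0.617.

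**Figure D2:**
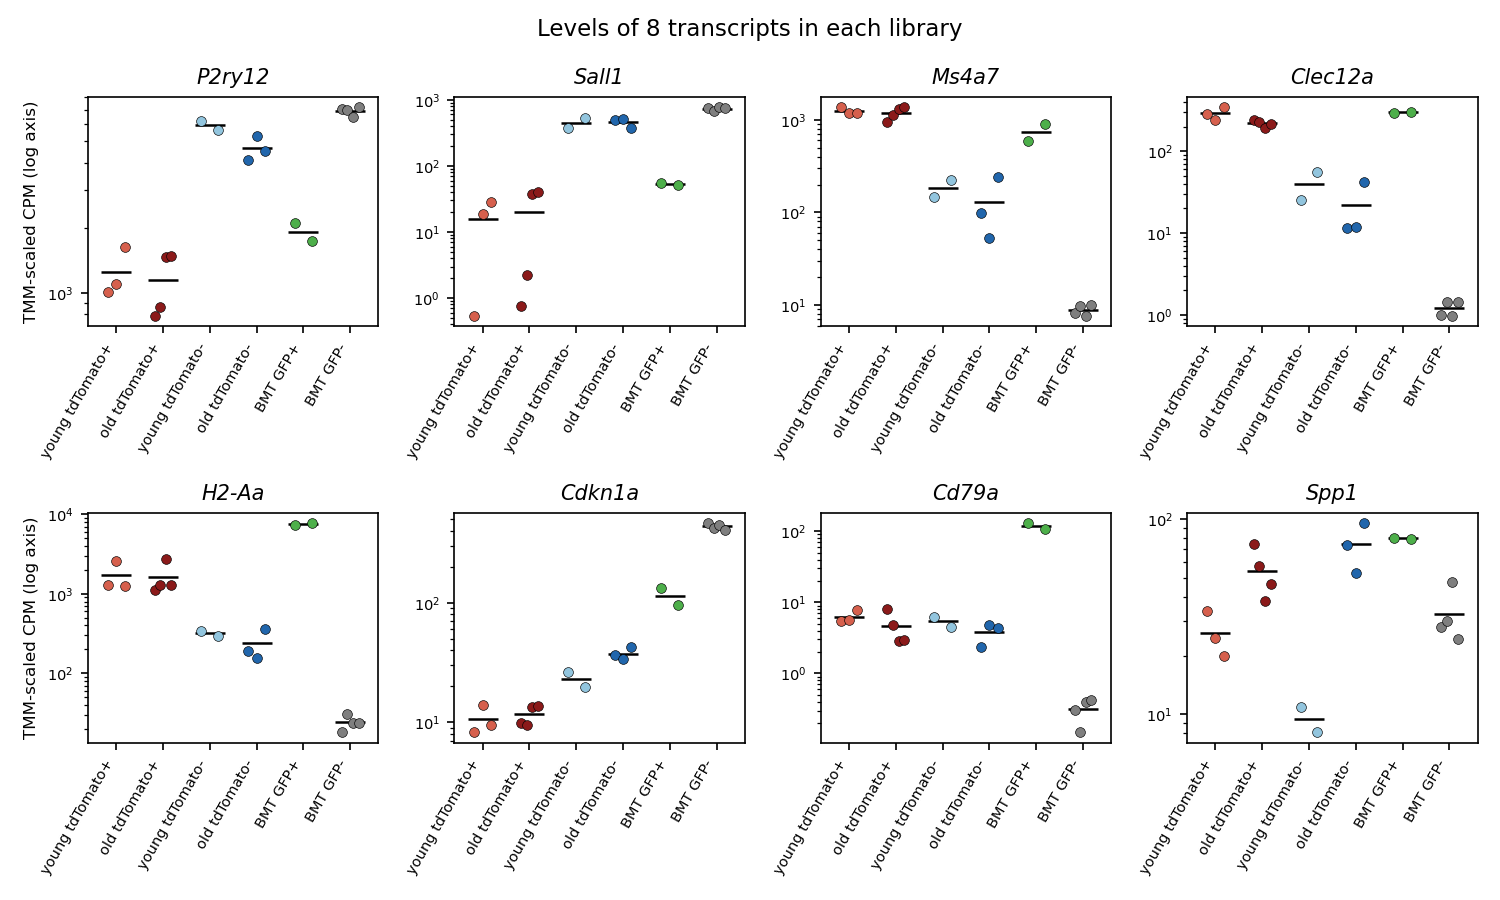
TMM-scaled CPM of 8 transcripts on log axes, with 1 point per library and a bar at each group's mean. P2ry12 and Sall1 are lower in all tdTomato+ and GFP+ libraries than in the tdTomato- and GFP- libraries, Ms4a7, Clec12a and H2-Aa are higher, and Cdkn1a is highest in the GFP- libraries.

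The tdTomato effect was then taken at each age, to ask whether the difference depends on age. In young mice 911 genes were higher and 1049 lower in tdTomato+ cells, and in old mice 1431 and 1576. With the replicate numbers as a block in edgeR, the young count fell from 1960 to 1505 and the old count from 3007 to 1379. In that fit only numbers with both reporter states inform the effect, which are 2 and 3 in young and 3 and 5 in old mice. The fall may thus reflect libraries that no longer count. With the block in limma the counts were higher, at 2483 in young and 3381 in old mice. Arhgap19 rose by 2.18 ± 0.17 (SE) on the log2 scale in young mice and by 2.20 ± 0.14 in old mice, and Tmem176b by 1.78 ± 0.15 and 1.86 ± 0.12. Slc12a2 fell by 2.89 ± 0.22 and by 2.86 ± 0.19. The fold changes of both ages correlated at r = 0.447 (rho = 0.49) across genes, from separate libraries. Of the called genes, 754 were higher and 890 lower at both ages, where independent lists would share 63.8 and 80.9, and 0 had opposite directions by edgeR where independence gives 144. The homeostatic list had 17 and 18 of 20 members lower and 1 higher in young and old mice, with 2 and 1 not passing. The engrafted macrophage list had 13 of 15 higher and 2 not passing at each age. Both counts were the same adjusted over the list alone, and both lists passed at each age with an estimated correlation (adjusted p = 0.0214 and 0.019 for the first list, 0.0172 and 0.0163 for the second). The test of the difference between ages called 0 genes with edgeR, where 776 had an unadjusted p under 0.05, DESeq2 called 4 and limma-voom called 0. Spp1, which encodes osteopontin, had the difference with log2 value -1.91 ± 0.42 (SE), and its edgeR adjusted p was 1. It passed with DESeq2 (0.042), with no filter on low counts (1.1e-09) and with the replicate numbers as a block in edgeR (-2.235, adjusted p = 0.0234), and its adjusted p ranged from 1.1e-09 to 1 over its alternatives. With no filter its log2 value was nearly the same (-1.916), so that call comes through the fitted spread and is no firmer evidence. The young count fell from 1960 to 1224 without the young tdTomato- library 2, to 1196 without that library and a further library rich in choroid plexus transcripts, and to 1199 when the fit held these groups only. The difference between ages gave 2 genes without the young tdTomato+ library 3, 6 without the young tdTomato- library 3, and 228 with no filter on low counts.

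After BMT, GFP+ donor cells were compared with GFP- host cells, mostly from the same pools of mice. The GFP+ cells had far more of the antigen presentation transcripts, and bulk counts cannot show which of the sorted cells carried them. H2-Aa was at 7528 ± 296 CPM (SD, n = 2) in GFP+ cells and 24.3 ± 5.33 CPM (SD, n = 4) in GFP- cells. Clec12a was at 299 ± 2.71 CPM (SD, n = 2) against 1.21 ± 0.261 CPM (SD, n = 4), and Ms4a7 at 743 ± 222 CPM (SD, n = 2) against 8.96 ± 1.18 CPM (SD, n = 4). P2ry12 was at 1920 ± 251 CPM (SD, n = 2) against 6921 ± 326 CPM (SD, n = 4). Sall1 was at 53.5 ± 2.74 CPM (SD, n = 2) against 738 ± 44.6 CPM (SD, n = 4), yet its log2 fold change of -3.79 ± 1.47 (SE) did not pass in edgeR (adjusted p = 0.0602). The fit shares its spread with the tdTomato+ libraries, where Sall1 ranged from 0.534 to 39.7 CPM. In edgeR on the BMT libraries alone its adjusted p was 2.35e-07, with DESeq2 it was 0.00675, with the pools as a block it was 6.34e-07 (edgeR) and 0.00279 (limma), and over all its alternatives it ranged from 2.72e-72 to 0.219.

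With edgeR 4089 genes were higher and 3563 lower in GFP+ cells, 2938 and 2001 of them at least 2-fold. Cnn2, a calponin gene, had the smallest adjusted p (log2 fold change 3.68 ± 0.16 SE, edgeR adjusted p = 7.73e-11), at 216 ± 1.17 CPM (SD, n = 2) against 16.8 ± 0.597 CPM (SD, n = 4). Plbd1 (8.55 ± 0.36), Cxcr3 (3.60 ± 0.18) and the cathepsin E gene Ctse (5.36 ± 0.26) followed, each with an edgeR adjusted p of 1.58e-10. Among the lower genes were P3h2 (-3.47 ± 0.21, edgeR adjusted p = 1.36e-09), P2ry13 (-2.02 ± 0.13, 1.62e-09) and Entpd1, which encodes the ATP-degrading enzyme CD39 (-2.11 ± 0.15, 7.76e-09).

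In this model 17 of 20 homeostatic microglia genes fell and 3 did not pass (20 lower adjusted over the list alone), and 14 of 15 engrafted macrophage genes rose and 1 did not pass (14 adjusted over the list alone). All 10 MHC class II genes rose (10 adjusted over the list alone). Classical monocyte markers rose in 8 of 10 cases with 2 not passing, non-classical monocyte markers in 6 of 7 with 1 not passing, dendritic cell markers in 8 of 9 with 1 not passing and B cell markers in 7 of 7, each with the same count adjusted over the list alone. Ccr2, the receptor that brings monocytes out of the marrow, was at 733 ± 130 CPM (SD, n = 2) against 8.35 ± 0.544 CPM (SD, n = 4), Cd209a, a dendritic cell lectin gene, at 467 ± 58.6 CPM (SD, n = 2) against 0.023 ± 0.0461 CPM (SD, n = 4), and Cd79a, part of the B cell receptor, at 118 ± 16 CPM (SD, n = 2) against 0.315 ± 0.122 CPM (SD, n = 4). MHC class I genes rose in 10 of 12 cases, fell in 1 and did not pass in 1 (10 and 1 adjusted over the list alone). Chemokine and adhesion receptors rose in 10 of 14, fell in 3 and did not pass in 1 (11 and 3 adjusted over the list alone). Genes of the p53 response fell in 8 of 18 cases, rose in 1 and did not pass in 9 (9 and 1 adjusted over the list alone). Cdkn1a, which encodes the cell cycle inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), was at 113 ± 26.1 CPM (SD, n = 2) in GFP+ cells and 435 ± 24 CPM (SD, n = 4) in GFP- cells. These 10 lists passed in camera with the preset and with the estimated correlation, where the adjusted p ranged from 0.0246 to 0.0485.

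Interferon response genes rose in 20 of 21 cases with 1 not passing (20 adjusted over the list alone), with Ifitm3 higher by 4.39 on the log2 scale, and the camera call (8.59e-13) was lost at adjusted p = 0.06 with an estimated correlation. Genes of oxidative phosphorylation rose in 15 of 15 cases (15 adjusted over the list alone), among them Cox5a by 1.43, and this call (1.53e-07) was lost at adjusted p = 0.152 with an estimated correlation. Lysosomal genes fell in 8 of 18 cases, rose in 1 and did not pass in 9 (8 and 1 adjusted over the list alone). The protease gene Ctsl fell by 1.70 on the log2 scale, and the call (0.00306) was lost at adjusted p = 0.211 with an estimated correlation. Border-associated macrophage genes rose in 10 of 13 cases and 3 did not pass (10 higher and 1 lower adjusted over the list alone), a call (2.42e-06) lost at adjusted p = 0.0714 with an estimated correlation. Beside these groups, all 10 T and NK cell markers were higher (10 adjusted over the list alone; camera 4.63e-09, adjusted p = 0.0766 with an estimated correlation). The NK cell receptor gene Klrd1 was at 49.5 ± 16.1 CPM (SD, n = 2) against 1.5 ± 0.709 CPM (SD, n = 4). All 6 erythroid markers were higher as well (6 adjusted over the list alone; camera 3.98e-05, adjusted p = 0.118 with an estimated correlation), and made up 1.45% and 0.932% of the counts of the GFP+ libraries against at most 0.0018% in GFP- libraries.

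Both label effects were set side by side, from libraries that do not overlap. Across the 20432 genes the log2 fold changes of tdTomato+ against tdTomato- and of GFP+ against GFP- correlated at r = 0.404 (rho = 0.426), and at r = 0.63 over the genes past a stricter filter. In both models 1336 genes were higher and 1196 lower, where independent lists would share 434 and 383. Opposite directions were called for 120 genes higher in tdTomato+ and lower in GFP+ cells and for 72 the other way, where independence gives 818 in all. Ms4a7, Clec12a, Apoe and H2-Aa rose in both models and P2ry12 fell in both.

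**Figure D3:**
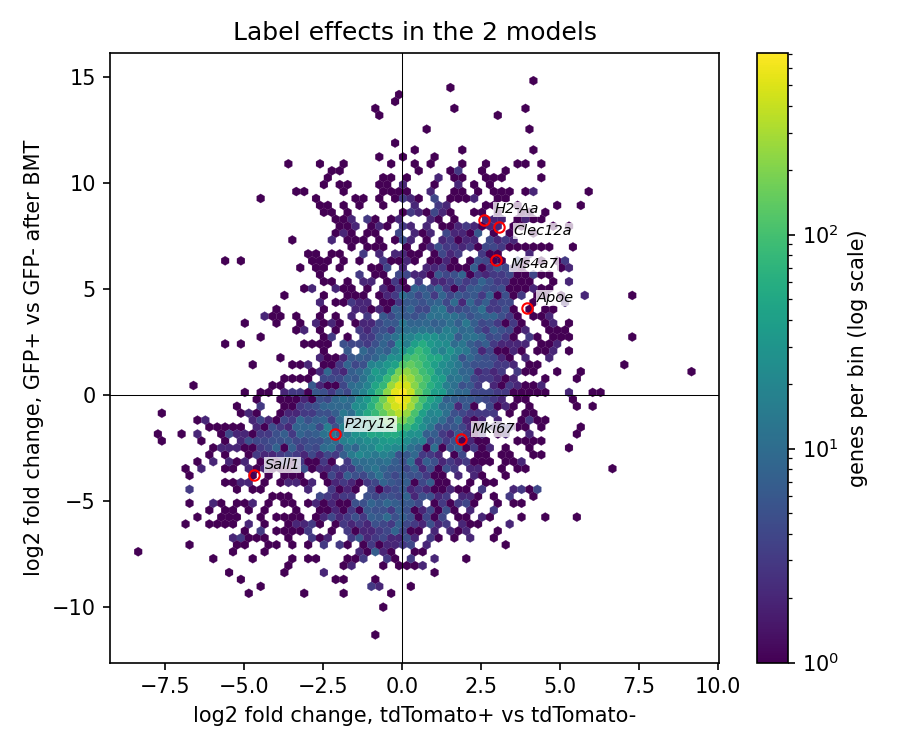
Log2 fold changes of the 20432 tested genes, with tdTomato+ against tdTomato- on the horizontal axis and GFP+ against GFP- after BMT on the vertical axis, coloured by the number of genes per bin on a log scale. Ms4a7, Clec12a, Apoe and H2-Aa lie at the upper right and P2ry12 at the lower left, and the correlation is r = 0.404.

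The difference of these effects, an interaction term, asked which genes depend on the model. MHC class II genes had a larger effect after BMT in 10 of 10 cases (10 adjusted over the list alone), with H2-Aa at a log2 difference of 5.68 ± 0.48 (SE, edgeR adjusted p = 2.96e-06). B cell markers were larger in 7 of 7 (7 adjusted over the list alone), dendritic cell markers in 7 of 9 with 2 not passing (7) and classical monocyte markers in 5 of 10 with 5 not passing (5). These 4 lists passed with an estimated correlation (adjusted p = 0.0205 to 0.0282). Ms4a7 (3.40 ± 0.48, edgeR adjusted p = 0.000206) and Clec12a (4.86 ± 0.54, 3.69e-05) had larger effects after BMT, and their GFP- levels were below their tdTomato- levels. P2ry12 (0.28 ± 0.28, edgeR adjusted p = 0.539), Tmem119 (-0.42 ± 0.19, 0.131) and Apoe (0.13 ± 0.74, 0.945) did not pass, which does not show that their effects were equal. The Tmem119 difference passed with the replicate numbers as a block in edgeR (-0.56, adjusted p = 0.0335) and without the libraries rich in choroid plexus transcripts (-0.64, 0.0375), and its adjusted p ranged from 0.0335 to 0.424 over its alternatives. Genes with the smallest adjusted p were Fgr, a Src family kinase gene (5.01 ± 0.29, edgeR adjusted p = 1.59e-08), Cd79a (8.29 ± 0.49, 2.49e-08) and, in the opposite direction, Fcrls (-2.07 ± 0.17, 4.88e-07), which was higher in tdTomato+ than in tdTomato- cells and lower in GFP+ than in GFP- cells. Lysosomal genes had a lower value after BMT in 11 of 18 cases and 7 did not pass (13 lower adjusted over the list alone), a camera call (3.06e-08) lost at adjusted p = 0.0606 with an estimated correlation. In all, 2327 genes had a higher and 2129 a lower label effect after BMT.

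Cells of bone marrow origin were also compared directly between the models. GFP+ cells had more transcripts of cell division, of the p53 response and of other blood cells than tdTomato+ cells. Cdkn1a was at 113 ± 26.1 CPM (SD, n = 2) in GFP+ and 11.2 ± 2.45 CPM (SD, n = 7) in tdTomato+ cells (log2 fold change 3.36 ± 0.17 SE, edgeR adjusted p = 3.89e-10). The cyclin gene Ccnb2 was at 21.6 ± 2.28 CPM (SD, n = 2) against 1.27 ± 0.357 CPM (SD, n = 7), and Rrm2, a subunit of ribonucleotide reductase, at 42 ± 6.57 CPM (SD, n = 2) against 3.55 ± 1.45 CPM (SD, n = 7). Mki67 did not pass, at 0.823 ± 0.303 CPM (SD, n = 2) against 0.562 ± 0.513 CPM (SD, n = 7; edgeR adjusted p = 0.481). Plac8, a gene abundant in monocytes, was at 248 ± 37.9 CPM (SD, n = 2) against 0.769 ± 0.493 CPM (SD, n = 7). Of the engrafted macrophage list 3 of 15 genes were higher in GFP+ cells, 5 lower and 7 did not pass (3 and 5 adjusted over the list alone), and the list was not called (camera adjusted p = 0.413). Clec12a (0.25 ± 0.39, edgeR adjusted p = 0.654), Ms4a7 (-0.71 ± 0.39, 0.174) and Apoe (-1.16 ± 0.61, 0.16) were among those that did not pass. Ms4a7 passed on the libraries of the groups compared alone (0.00923) and with no filter on low counts (0.00015), and Apoe with the library series as a term (0.0346) and with no filter (2.45e-09). Over their alternatives the adjusted p ranged from 0.00015 to 0.585 and from 2.45e-09 to 0.529. Lyz2 was higher (1.18 ± 0.39, edgeR adjusted p = 0.0301) and Mrc1 lower (-1.45 ± 0.49, 0.035). Lyz2 lost its call without the GFP+ libraries 1 (0.0841) and 2 (0.194) and with the series term (0.0613), within a range from 8.39e-13 to 0.194. Mrc1 lost its call without the GFP+ libraries 1 (0.22) and 2 (0.102), the young tdTomato+ library 2 (0.0558) and the old tdTomato+ library 2 (0.0513), within a range from 3.74e-15 to 0.22.

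With edgeR 3805 genes were higher and 3247 lower in GFP+ cells, led by Cnn2 (3.49 ± 0.13, edgeR adjusted p = 9.1e-12), the small GTPase gene Rac2 (1.94 ± 0.10, 3.89e-10) and Fgr (3.94 ± 0.20, 3.89e-10). The lower genes were led by Dbp (-3.08 ± 0.22, edgeR adjusted p = 2.81e-08) and Nr1d1 (-4.81 ± 0.38, 1.53e-07), which belong to the circadian clock. The proliferation list had 17 of 20 members higher and 3 not passing (17 adjusted over the list alone), and the p53 list 9 higher, 1 lower and 8 not passing of 18 (11 and 2 adjusted over the list alone). Its Phlda3 was higher by 4.26, Bax, a cell death gene, by 1.02, and Eda2r was at 1.42 ± 0.0804 CPM (SD, n = 2) against 0.00746 ± 0.0197 CPM (SD, n = 7), where the tdTomato+ libraries held 2 counts in all. B cell markers were higher in 7 of 7 (7 adjusted over the list alone), dendritic cell markers in 7 of 9 with 2 not passing (8) and classical monocyte markers in 7 of 10 with 3 not passing (8). These 5 lists passed with an estimated correlation (adjusted p = 0.0056 to 0.049). Lysosomal genes were lower in 13 of 18 cases and 5 did not pass (14 adjusted over the list alone). Grn, which encodes progranulin, fell by 1.22, and the camera call (4.29e-08) was lost at adjusted p = 0.0626 with an estimated correlation. MHC class II genes were higher in 9 of 10 cases with 1 not passing (9 adjusted over the list alone), a call (4.29e-08) lost at the same adjusted p = 0.0626 with an estimated correlation. Beside these groups T and NK cell markers were higher in 10 of 10 cases (10 adjusted over the list alone; camera 1.21e-10, adjusted p = 0.0626 with an estimated correlation) and erythroid markers in 6 of 6 (6; camera 0.000498, adjusted p = 0.283 with an estimated correlation). The homeostatic list was higher in 5, lower in 9 and not past the test in 6 of 20 cases (5 and 9 adjusted over the list alone), and was not called. The count of 7052 rests on 2 GFP+ libraries and fell when either was left out. The labels name no batch, but the library numbers of the BMT libraries all come before those of the tdTomato libraries. A batch that follows this order could not be told apart from the model in any comparison between the models.

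Host cells of the BMT mice were compared with tdTomato- cells to see how the unlabelled cells differ between the models. GFP- cells had more p53 target transcripts. Cdkn1a, with the smallest adjusted p in the comparison, was at 435 ± 24 CPM (SD, n = 4) in GFP- and 31.8 ± 8.81 CPM (SD, n = 5) in tdTomato- cells (log2 fold change 3.89 ± 0.17 SE, edgeR adjusted p = 1.95e-10). Bax was at 82.2 ± 1.69 CPM (SD, n = 4) against 37.1 ± 6.18 CPM (SD, n = 5), and the cyclin G1 gene Ccng1 at 142 ± 17.8 CPM (SD, n = 4) against 42.1 ± 5.7 CPM (SD, n = 5). The p53 list had 11 of 18 members higher and 7 not passing (12 higher and 1 lower adjusted over the list alone), with a camera adjusted p of 2.76e-15 and an adjusted p = 0.00019 with an estimated correlation. Transcripts of engrafted macrophages were at lower levels in GFP- cells, with Ms4a7 at 8.96 ± 1.18 CPM (SD, n = 4) against 152 ± 79.3 CPM (SD, n = 5).

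In edgeR 970 genes were higher and 1183 lower in GFP- cells, so that 45.1% of the calls were higher, a share that was 52% with RLE factors. The higher genes included Gas6 (1.60 ± 0.15, edgeR adjusted p = 2.49e-06) and Fcrls (1.08 ± 0.11, 3.26e-06). The lower genes included Tnfsf8 (-2.41 ± 0.13, edgeR adjusted p = 3.54e-09), P2ry14 (-3.92 ± 0.25, 2.74e-08) and Axl, the receptor that Gas6 binds (-2.38 ± 0.18, 2.35e-07). The engrafted macrophage list fell in 11 of 15 cases and 4 did not pass (12 lower adjusted over the list alone). Proliferation genes rose in 11 of 20 cases and 9 did not pass (16 higher adjusted over the list alone). Ccnb2 was at 5.27 ± 0.956 CPM (SD, n = 4) against 1.59 ± 0.654 CPM (SD, n = 5). Mki67, with 2 counts in all in the young tdTomato- libraries, was at 3.53 ± 0.158 CPM (SD, n = 4) against 0.445 ± 0.535 CPM (SD, n = 5). Chemokine and adhesion receptors fell in 6 of 14 cases and 8 did not pass (9 lower and 2 higher adjusted over the list alone). These 3 lists passed with an estimated correlation (adjusted p = 0.0422, 0.0343 and 0.0422). MHC class II genes fell in 8 of 10 cases and 2 did not pass (8 adjusted over the list alone; camera 3e-09, adjusted p = 0.0967 with an estimated correlation). Homeostatic genes rose in 6 of 20 cases and 14 did not pass (6 adjusted over the list alone; camera 5.21e-06, adjusted p = 0.184 with an estimated correlation). Beside these groups, erythroid markers were lower in 6 of 6 cases (6 adjusted over the list alone; camera 2.18e-06, adjusted p = 0.188 with an estimated correlation), and T and NK cell markers were higher in 4 of 10 with 6 not passing (8 adjusted over the list alone; camera 0.000204, adjusted p = 0.378 with an estimated correlation). The mean log2 CPM of the T and NK cell list also moved with the library series among tdTomato- cells, at 0.207 in the library numbered 11 and -2.538 to -1.119 in those numbered 15 to 20, against 0.749 to 2.272 in GFP- libraries. The count of 2153 fell to 1365 without the GFP- library 3, to 888 with the library series as a term and to 1226 without the libraries rich in choroid plexus transcripts.

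**Figure D4:**
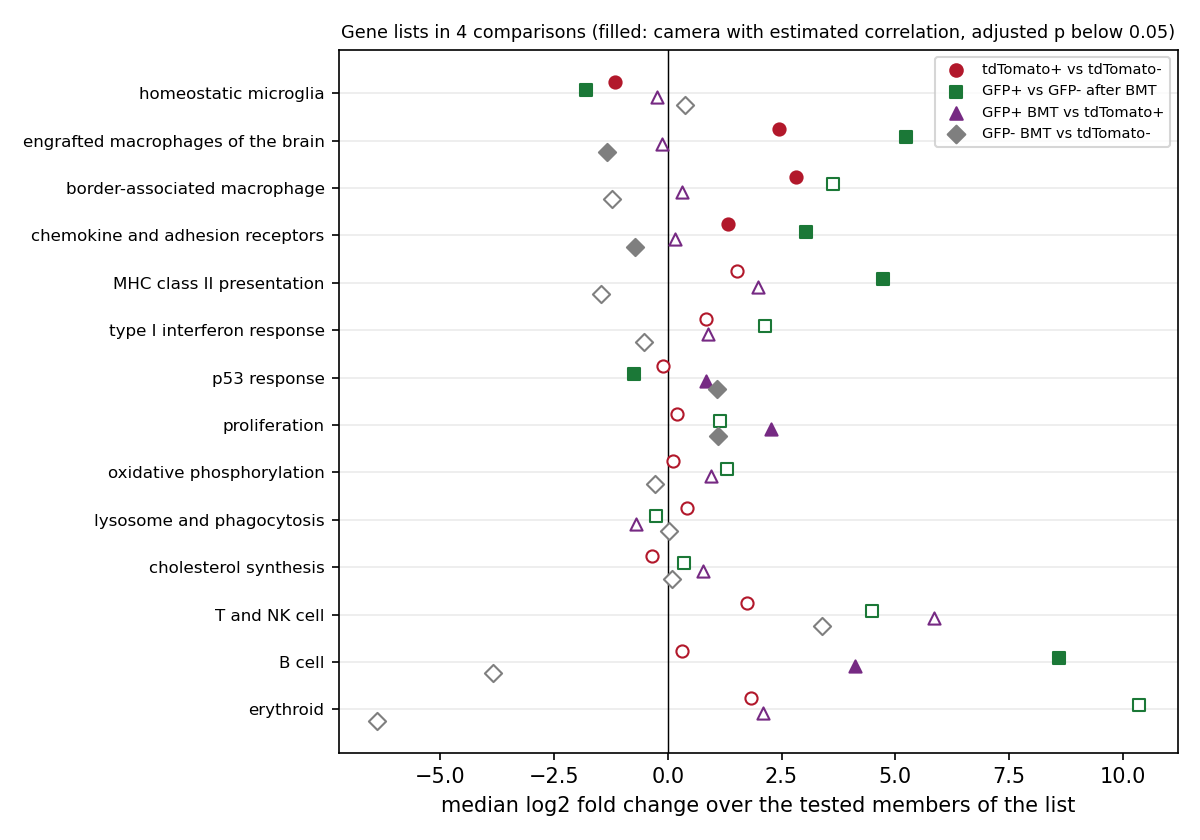
Median log2 fold change of the tested members of 14 gene lists (horizontal axis) in 4 comparisons, marked by shape and colour, with filled symbols where camera with an estimated correlation had an adjusted p below 0.05. The homeostatic list is at -1.16 for tdTomato+ against tdTomato- and -1.81 for GFP+ against GFP-, and the p53 list at 1.07 for GFP- against tdTomato-.

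Age was tested within each reporter state. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) was at 74.2 ± 21.1 CPM (SD, n = 3) in old and 9.51 ± 2.01 CPM (SD, n = 2) in young tdTomato- cells, a log2 fold change of 2.97 ± 0.36 (SE, edgeR adjusted p = 0.00389). In tdTomato+ cells it was at 54.1 ± 15.8 CPM (SD, n = 4) in old and 26.1 ± 7.02 CPM (SD, n = 3) in young mice and did not pass (1.05 ± 0.27, edgeR adjusted p = 0.741), except with no filter on low counts (6.29e-07), within a range from 6.29e-07 to 1. The other 2 genes called in tdTomato- cells were named after their values were seen. BC064078 (ENSMUSG00000087150, chromosome 6, 128992952 to 129008040) was at 1.85 ± 0.523 CPM (SD, n = 3) in old against 7.75 ± 0.417 CPM (SD, n = 2) in young cells (-2.06 ± 0.33, edgeR adjusted p = 0.0425). Gzma, which encodes the cytotoxic protease granzyme A (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981), was at 3.90 ± 2.52 CPM (SD, n = 2) in young cells, while the old libraries held 1 count in all (edgeR adjusted p = 0.0425). The T and NK cell list moved with it, at a mean log2 CPM of 0.207 and -1.119 in young against -2.538 to -2.477 in old libraries, with 10 of 10 members not passing and 1 lower adjusted over the list alone. Age and library series are largely tied together here. All old tdTomato- libraries belong to the later series, as does the young library at -1.119, while the young library at 0.207 belongs to the earlier series. With the series as a term the age comparison in tdTomato- cells called 3 genes. Its camera call (0.00279) was lost at adjusted p = 0.529 with an estimated correlation. The proliferation list in tdTomato- cells had 20 of 20 members not passing and 4 higher adjusted over the list alone, with Rrm2 at 4.17 ± 0.771 CPM (SD, n = 3) in old and 0.985 ± 0.285 CPM (SD, n = 2) in young cells (edgeR adjusted p = 0.217). Rrm2 passed with DESeq2 (0.000411) and with no filter on low counts (1.11e-05), within a range from 1.11e-05 to 0.707. The camera call for the list (0.000908) was lost at adjusted p = 0.459 with an estimated correlation. In all, camera called 10 lists between old and young tdTomato- cells, and 0 of them held with an estimated correlation. Among the 10 were the erythroid, the astrocyte and the choroid plexus and ependyma lists.

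In tdTomato+ cells edgeR called 0 genes between old and young mice, with 999 at an unadjusted p under 0.05, while DESeq2 called 26, limma-voom 0 and edgeR with no filter on low counts 191. That count was 1 without the young tdTomato+ library 2 and 4 without the young tdTomato+ library 3. In tdTomato- cells edgeR called 3 genes, with 1532 at an unadjusted p under 0.05, DESeq2 75, limma-voom with quality weights 0 and edgeR with no filter 465. The count was 0 without the young tdTomato- library 2, where the adjusted p of Spp1 became 0.166, 16 without the young tdTomato- library 3, and 1 each without the old tdTomato- libraries 3 and 4. Spp1 had an adjusted p of 0.183 with quality weights and of 0.215 without the libraries rich in choroid plexus transcripts, and ranged from 1.14e-35 to 0.215 over its alternatives. Gzma and BC064078 lost their calls without the young tdTomato- library 2 (0.234 each) and without the old tdTomato- libraries 3 (0.528 each) and 4 (0.28 each). Both also lost their calls with quality weights (0.376 for Gzma and 0.3 for BC064078), with the replicate block in limma (0.36 and 0.23) and without the libraries rich in choroid plexus transcripts (0.258 each). Gzma also lost its call without the old tdTomato- library 5 (0.171), and BC064078 without the young tdTomato- library 3 (0.0652) and on the libraries of the groups compared alone (0.161). Over their alternatives the adjusted p ranged from 1.13e-65 to 0.528 for Gzma and from 7.05e-09 to 0.528 for BC064078.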

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

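The tests on a lower share of macrophages, on other blood cells of the donor and on dissociation were chosen after the result was seen, while the tests on carried host microglia and on cells like the tdTomato+ cells and the split tests were set beforehand, except that the rule by which splits of GFP- against tdTomato- cells count as different was changed after a first result was seen.

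Transcripts of other blood cells were higher in GFP+ BMT cells than in tdTomato+ cells. A lower share of macrophages with brain cells in their place would raise markers of brain cells. The 42 brain cell markers had a median log2 fold change of -1.49 (95% interval of the median across genes -1.85 to -1). Their median was -1.47 with the 3 members empty on one side set at their bound. The median of 28 blood cell markers was 5.19 (3.29 to 5.57). This argues against brain cells in place of macrophages, but not against other donor cells, which the GFP+ sort also keeps. Other blood cells of the donor in the GFP+ sort remain open as a source, and 22 of 23 members of the T and NK cell, B cell and erythroid lists (95.7%) lay above every tdTomato+ library in both GFP+ libraries, with Alas2 the exception, which restates the pattern and does not support that source. Among them were Hbb-bs at 3880 ± 954 CPM, Nkg7 at 391 ± 21.4 CPM and Igkc at 287 ± 110 CPM (SD, n = 2), and Ighm at 886 ± 6.36 CPM (SD, n = 2), which was also abundant in tdTomato+ (402 ± 49.3 CPM, SD, n = 7) and GFP- cells (518 ± 92.2 CPM, SD, n = 4). The gate for CD11b and against CD44 may remove many of these cells, but the purity of the sort was not measured here. Transcripts of proteins that the gate excluded were present in GFP+ libraries 1 and 2, with Cd44 at 111 and 71.7 CPM and Ly6c2 at 75.1 and 74.4 CPM. The gate thus does not decide which other blood cells were present. GFP- host cells also held 8 of 10 T and NK cell, 2 of 7 B cell and 0 of 6 erythroid transcripts at 1 CPM in each library. All members of these lists were called lower there than in GFP+ cells, with Nkg7 at 9.46 ± 6.45 CPM (SD, n = 4). A difference of the engrafted cells themselves between the models remains untested.

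Transcripts of p53 targets were higher in BMT cells than in cells of the tdTomato model, in both reporter states. For the 9 p53 members that rose, carried host microglia would need to make up a median of 63% and 41.2% of the GFP+ libraries 1 and 2. The SD over members divided by root n was 9.14 and 9.91. Single members needed 27.6% (Aen) to 104% (Btg2) in library 1 and 10.6% (Ccng1) to 91.8% (Btg2) in library 2. They were picked by their rise in these same libraries, which tends to raise the needed share. The Sall1 level allows 7.52% and 6.99%, which argues against host microglia carried into the GFP+ sort as the source for these members. A response to dissociation would raise immediate early genes, but the 17 tested members had a median log2 fold change of -0.46 (95% interval -0.63 to 0.12) in GFP- against tdTomato- cells, where the p53 list had 1.07, while in GFP+ against tdTomato+ cells their median of 0.18 (-0.3 to 1.15) against 0.83 leaves such a response open. Irradiation and transplantation in one model, or PLX5622, which by elimination the mice of the other model received, may underlie the pattern as hypotheses that were not tested. The library numbers of the BMT libraries all come before those of the tdTomato libraries, so neither can be told apart from a batch that follows the model.

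Transcripts of monocyte-derived brain macrophages were higher in tdTomato- than in GFP- cells. Cells like the tdTomato+ cells in the tdTomato- sort may account for part of this. The 115 genes at 20 CPM or more in tdTomato+ cells and at least 10 times above GFP- cells needed a median share of 12.7% (quartiles 9.63 to 17.1). Of them 0% needed less than 20% of the median share, which met the rule set beforehand. A cut so low cannot show that the share was even over genes. Shares ran from 2.87% for Iqgap2 to 48.3% for Arhgap15. Apoe, Mrc1 and Lyz2 needed 4%, 4.33% and 5.93%, and Ms4a7 and H2-Aa 11.9% and 15%. The red cell genes Hba-a2, Hba-a1, Alas2, Hbb-bt, Hbb-bs and Slc4a1 needed 30.8% to 39.3%, more than such cells at the median share would bring. Per library the median share was 10.5% and 17.6% in young tdTomato- libraries 2 and 3 and 7.58%, 5.54% and 17.5% in old tdTomato- libraries 3, 4 and 5. Such cells could be progeny of the marrow in which the reporter did not recombine, or sorting carry-over, and these were not tested apart. A lower level in GFP- cells because of the transplant or of a batch that follows the model remains open as well.

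Regrouping the libraries asked whether other splits call as many genes. The real split had the most calls for tdTomato+ against tdTomato-, with 4367 and at most 2019 in the other splits drawn (1 of 100 as large, the real split included). The same held in old mice, with 3007 and at most 1149 (1 of 35), and for GFP- against tdTomato-, with 2153 and at most 1562 (1 of 100). Chance is thus an unlikely source of these counts, but the splits take no account of the library series or of shared mice. For old against young tdTomato+ cells 0 genes were called by edgeR with 999 at an unadjusted p under 0.05, 26 by DESeq2 and 0 by limma-voom, so each of the 35 splits had to give at least as many and the count says nothing about chance. The split with the most calls there, 607, follows the library series (numbers 8 to 13 against 15 to 21), which was defined after seeing the data. The series term itself called 0 genes in the edgeR fit of all libraries, with 2445 at an unadjusted p under 0.05. A structure of the samples by series remains open. With the series as a term that age comparison called 0 genes.

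The effect of the reporter differed between the models in 4456 genes by the interaction test, and values are BMT minus tdTomato on the log2 scale. Larger effects after BMT were seen for Cxcr3 (1.18), Ms4a7 (3.40), Clec12a (4.86), Lyz2 (2.75), H2-Ab1 (5.49), H2-Aa (5.68), Il1b (2.23) and Alas2 (7.83). Such a difference can come from the unlabelled cells. Ms4a7 was at 8.96 CPM in GFP- against 152 CPM in tdTomato- cells, Clec12a at 1.21 against 29.2 CPM and H2-Aa at 24.3 against 270 CPM. Between GFP+ and tdTomato+ cells Ms4a7 and Clec12a did not pass, while H2-Aa was higher in GFP+ cells. P2ry13 was at -0.85. Mki67 was at -3.97, a fitted value that rests on 2 counts in the young tdTomato- libraries.

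Single libraries stood apart from the rest of their group in 5 of 126 values tested, where chance gives about 1 in 20, or 6.3. The gap to the next library, as a share of the range, was 0.848 for Oasl2 in old tdTomato+ library 2, 0.923 for Cnn2 in old tdTomato+ library 3, 1 for Eda2r in old tdTomato+ library 2, 1 for Cd209a in GFP- library 3 and 0.87 for Adgrl2 in GFP- library 4. Eda2r and Cd209a rest on 2 and 4 counts.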

How the results depend on the processing

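The fits with the library series as a term and without the libraries rich in choroid plexus transcripts were chosen after the result was seen. Named genes gave 170 pairs of a gene and a comparison, in which a gene named in several comparisons counts once for each. Of 3327 values of these pairs under the alternatives, 3237 kept their direction and side of the threshold, 46 lost and 44 gained a call and 0 reversed. DESeq2 called 4 genes for the difference between ages, 26 for age in tdTomato+ and 75 for age in tdTomato- cells. No filter, with 37346 genes tested, called 228, 191 and 465. Fold changes of named genes that gained a call there stayed close to the main fit. Sall1 in GFP+ against GFP- cells kept a log2 value of -3.838 while its edgeR adjusted p went from 0.0602 to 2.72e-72. Such calls come through a smaller fitted spread rather than through the effect, and were not taken as firmer evidence. For age in tdTomato- cells the stricter filter called 5, limma-voom with quality weights 0, and the fit without choroid-rich libraries 0. For tdTomato+ against tdTomato- in young mice the fit on the compared groups alone called 1199 and the fit without choroid-rich libraries 1196. For GFP- against tdTomato- cells the series term gave 888 and leaving out choroid-rich libraries 1226. Camera with an estimated correlation kept 35 of 126 list calls. The correlation between models was 0.63 with the stricter filter and 0.426 as Spearman's rho, and the first component held 29.1% over all genes. The cause was not tested for these. The tdTomato libraries share replicate numbers, and the labels do not say whether same-numbered libraries come from the same mouse. Deviations from the group means of same-numbered libraries correlated at -0.013, -0.028, -0.126 and 0.344, which does not settle it. With the replicate block, edgeR called 2821 genes for tdTomato+ against tdTomato-, 1379 in old mice and 1 for the difference between ages. In limma the block gave 4895, 3381 and 0 for these, and 1 for age in tdTomato- cells. The block by pools changed no BMT count by over 1.5 times (6565 and 8623 against 7652), gave Sall1 a call and changed no other call among the genes named for GFP+ against GFP-. In fry it ended the myeloid progenitor call of that comparison (adjusted p = 0.0507 from 0.0466). As a fixed term in edgeR the block gave Tmem119 and Cdkn1a a call in the difference between models. Leaving out each library in turn gave 3578 to 4386 genes for tdTomato+ against tdTomato-, 1224 to 1811 in young and 2005 to 2925 in old mice, 0 to 6 for the difference between ages, 5776 to 7321 for GFP+ against GFP-, 4359 to 7114 for GFP+ against tdTomato+, 1365 to 2044 for GFP- against tdTomato-, 2986 to 4889 for the difference between models, 0 to 4 for age in tdTomato+ and 0 to 16 in tdTomato- cells, and 0.349 to 0.41 for the correlation between models. Where this left a group with 1 library, that library was assumed to vary like the others. RLE factors moved the median of all genes by at most 0.046.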

Other observations

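The values for clock genes, for the library series, for choroid plexus transcripts and for the genes of the gate were chosen after the result was seen.

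Several genes of the circadian clock and its output, picked after their values were seen and not tested as a list, differed between the models in both reporter states. Dbp, an output gene of the clock, was at 87 ± 16.8 CPM (SD, n = 7) in tdTomato+ and 10.4 ± 1.37 CPM (SD, n = 2) in GFP+ cells, and at 43.8 ± 11.7 CPM (SD, n = 5) in tdTomato- and 14.2 ± 2.57 CPM (SD, n = 4) in GFP- cells. The repressor gene Nr1d1 had log2 fold changes of -4.81 (GFP+ against tdTomato+, edgeR adjusted p = 1.53e-07) and -1.70 (GFP- against tdTomato-, 0.000191), Nr1d2 of -1.52 (1.3e-05) and -0.47 (0.0465), Per3 of -3.02 (2.31e-07) and -1.17 (0.000403), and Tef of -1.95 (3.46e-07) and -0.82 (0.000494). Arntl, an activator gene of the clock, was higher by 1.27 (edgeR adjusted p = 0.000665) and 0.71 (0.0471). Others did not follow in both states. Hlf, related to Dbp and Tef, did not pass in GFP+ cells (0.87, edgeR adjusted p = 0.389) and was higher in GFP- cells (2.48, 0.0201), Ciart was lower in GFP+ cells (-1.22, 0.0478) and did not pass in GFP- cells (-0.65, 0.289), and Npas2 passed in neither (0.283 and 0.679). Per1 (-1.453, edgeR adjusted p = 0.0278), Per2 (-2.487, 0.0117), Cry2 (-0.904, 0.00347) and Clock (-0.694, 0.00857) were lower in GFP+ cells and did not pass in GFP- cells (0.0851, 0.704, 0.0804 and 0.658), and Cry1 passed in neither (0.358 and 0.68). Bhlhe40, a repressor gene, was higher in GFP+ cells (1.217, edgeR adjusted p = 0.0051) and lower in GFP- cells (-1.5, 0.0026). The time of day of collection is not given in the labels used here, and no explanation was tested.

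Sall1 was uneven among the tdTomato+ libraries, at 0.534, 18.4 and 28.6 CPM in young libraries 1, 2 and 3 and at 0.764, 2.19, 37.7 and 39.7 CPM in old libraries 1, 2, 3 and 5. This follows the library series, since the libraries numbered 8 to 13 (young 1 and 2, old 1 and 2) were at 0.534 to 18.4 CPM and those numbered 15 to 21 at 28.6 to 39.7 CPM. The mean log2 CPM of the homeostatic microglia list was 7.717 to 8.558 in the former and 8.899 to 8.92 in the latter. Ttr, which encodes transthyretin and is abundant in the choroid plexus, was at 1340 CPM in young tdTomato- library 2 and 1300 CPM in GFP- library 1, against 10.9 to 285 CPM in the other 16 libraries. Transcripts of proteins that the gate excluded were present. Cd44 was at 44.7 to 80.4 CPM in tdTomato+ libraries, 17.6 to 36.6 CPM in tdTomato- libraries, 111 and 71.7 CPM in GFP+ libraries and 6.47 to 8.86 CPM in GFP- libraries. Ly6c2 was at 75.1 and 74.4 CPM in the GFP+ libraries and at most 0.791 CPM in the tdTomato libraries.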
